A study of Mus musculus with 18 samples.

How the data were processed

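RNA of MIN6 cells, a mouse beta cell line, was sequenced in 18 libraries. The cells had been treated for 24 h with vehicle, with 5 mM DFMO or with 10 µM DENSpm, each with or without a mix of the cytokines interferon gamma, tumour necrosis factor alpha and interleukin 1 beta. The labels give 6 groups of 3 libraries and call the replicates biological replicates. The p-values measure the spread between these libraries. Libraries were poly(A)-selected and strand-specific, made with a TruSeq protocol and sequenced on an Illumina NovaSeq instrument, per the labels' protocols.

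The deposited values were raw counts and normalised values, each in a table for the DFMO series and a table for the DENSpm series. The raw counts of reads per gene were made by the authors with HTSeq on the mm10 mouse genome, per the submitters' processing notes, which also name FastQC and DESeq2. Their versions were not given, and the aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. Each table had 24557 rows with a gene symbol and a gene ID. The 6 libraries without a drug stood in both tables with identical counts. The deposited normalised values were on the log2 scale. Within each library the raw count divided by the term (2 to the power of the value, less 1) gave a single factor for all rows, within 1e-9. These log2 values of the authors served only to recover their library factors. Date conversion had altered 26 symbols, and all 26 were repaired from the gene ID; 5 symbols stood on more than 1 row.

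Library totals ran from 403377 to 639625 counts, with a median of 480476.5, and 14840 rows held at least 1 count. At this depth a row with fewer than about 10 counts in a library carries a counting error as large as many differences tested here. A count of 2 was more frequent than a count of 1 (24598 against 15440 cells of the table), and a count of 4 more frequent than a count of 3 (13838 against 6502). A fit on halved counts was therefore among the alternatives. Intervals and lower bounds cover counting error only, and are too narrow if each read pair added 2 counts.

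Row symbols were matched to an annotation of the same assembly (GRCm38), and each row was classed by what lies on the other strand. Rows whose exons overlap exons of a gene on the opposite strand numbered 5838 and held 83.0% of all counts. Another 3112 rows overlapped only the body of such a gene and held 2.54%, 15229 rows faced no gene and held 9.54%, and 378 rows were not matched and held 4.93%. The 78 rows of ribosomal protein genes, which are among the most abundant poly(A) transcripts of any cell, held between 0.0826% and 0.163% of the counts of a library. For this reason a row is named by its symbol together with the gene whose exons it overlaps on the opposite strand, if any, and a change in a row is not stated as a change of the gene it is named for. Where overlapping rows lie opposite the same gene, as the rows of Pcsk2os1 and Pcsk2os2 do, their counts cannot be told apart.

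Differences between groups were tested with edgeR 4.0.16 (R 4.3.3; quasi-likelihood F test with robust estimation, TMM factors, filterByExpr by group) and adjusted with the Benjamini-Hochberg method. Rows with an adjusted p under 0.05 are counted as changed. Each comparison was fitted within the table that holds its groups, with a mean per group, so that all 12 libraries shared the estimate of the spread. The cytokine effect in vehicle was fitted in the DFMO table. DENSpm was compared with DFMO in a fit of all 18 libraries. After filtering, 3302 rows were tested in the DFMO table, 3315 in the DENSpm table and 3713 in the joined table, holding 96.6%, 96.6% and 97.1% of the counts. The common biological coefficients of variation were 0.26, 0.296 and 0.306. CPM, the counts scaled to a common library total, use TMM factors of the 18-library fit and are given as mean ± SD of 3 libraries; fold changes are on the log2 scale, ± a standard error derived from the F statistic.

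The fit was tested on simulated data with 200 rows changed by known factors. In the DFMO comparison (3302 rows) it recovered 15.2% of the rows raised 1.5-fold, 52.3% of those raised 2-fold, 80.9% of those raised 4-fold and 39.0% of those lowered to 0.5, and 6.67% of its calls were false. In the DENSpm comparison (3315 rows) the figures were 6.52%, 26.5%, 77.6%, 15.0% and 6.25%. The recovered shares are of changed rows that passed the filter in the simulated data. In the order above these numbered 46, 44, 47 and 41 for DFMO and 46, 49, 49 and 40 for DENSpm. Changed rows lost to the filter are not counted as missed.

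The design, the 18 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, per comparison, the 6 rising and 6 falling genes of largest change with a mean of at least 5 CPM, an established symbol and groups that do not overlap; up to 3 changed members of each list; and Odc1, Sat1, Smox, Azin1, Amd1, Srm, Sms, Ins1, Ins2 and Nos2 in every case. For interaction terms the groups may overlap. Chance alone separates 3 libraries from 3 others without overlap in 10% of comparisons. A second rule, set after values had been seen, names up to 6 rising and 6 falling rows with a mean of at least 100 CPM whose exons overlap exons of a protein-coding gene on the opposite strand. The text gives preference to rows whose call held in every fit that left out 1 library. Rows outside both rules were chosen after their values had been seen: Zmynd15, Pcsk2os1, Pcsk2os2, Primpol and Gse1, Exosc9 and Particl, and in some comparisons Psd, Emc9, Mars, Ints8, Tsr1, Rbbp4, Igf2os and 3110062M04Rik. Some rows that met these rules are not reported here. A row with no gene opposite is taken to hold the small share of reads counted on its own strand.

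The lists were polyamine metabolism, beta cell identity and secretion, interferon response, antigen presentation, NF-kB targets and chemokines, integrated stress response, ER chaperones and unfolded protein response, cholesterol synthesis, cell cycle, p53 targets, NRF2 and antioxidant, mitochondrially encoded genes, nuclear oxidative phosphorylation, ribosome biogenesis and MYC, glycolysis and hypoxia, other islet endocrine cells, non-endocrine pancreas with stroma and immune cells, and beta cell disallowed genes. They were tested with camera (limma 3.58.1; preset correlation 0.01, two-sided, adjusted over lists), beside camera with an estimated correlation and fry. They were tested by the symbol of the row, as fixed, and again by the gene opposite the row, which was added after the data had been seen. Cell cycle genes were also taken from the list of Seurat 5.3.0, a choice made after the data had been seen.

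Alternatives were DESeq2 1.42.0, RLE factors, the authors' library factors, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, fits of only the groups compared or of all 18 libraries, a minimum absolute log2 fold change of 1, each library left out in turn, halved counts, and only rows with an opposite exon; the last 2 were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.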

Results

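The effect of polyamine depletion on the response of beta cells to proinflammatory cytokines was examined by RNA sequencing of MIN6 cells, a line derived from mouse pancreatic beta cells. DFMO is an inhibitor of ornithine decarboxylase, the enzyme that makes the first polyamine, putrescine, and DENSpm is an analogue of the polyamine spermine that raises polyamine catabolism. Vehicle, DFMO (5 mM) and DENSpm (10 µM) were each tested without and with cytokines for 24 h, with 3 libraries per group. Mean totals were 550390 ± 71077.6 counts (SD, n = 3) in vehicle, 466986 ± 10876.9 in vehicle with cytokines, 470510 ± 35543.3 in DFMO, 453425 ± 44495.5 in DFMO with cytokines, 490414 ± 25321.9 in DENSpm and 525167 ± 100076 in DENSpm with cytokines. The leading 3 principal components of the 18 libraries held 25.8%, 13.2% and 6.44% of the variance.

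Most counts stood in rows that lie opposite another gene. Rows whose exons overlap exons on the opposite strand held between 80.3% and 84.9% of the counts of a library. Among 72 pairs of a gene and its named opposite-strand row with at least 100 counts, the opposite-strand row was the higher in 56 (77.8%). In the 38 of those pairs with at least 1000 counts in the opposite-strand row, the gene itself held a median of 0.797% of its partner's counts. Choosing pairs by a high count in the opposite-strand row favours a low value. Some pairs went the other way, among them Ccpg1 with 10957 counts against 10 and Pax6 with 2983 against 65 in the opposite-strand row. Pcsk2, which encodes a proinsulin-processing convertase, held 686 counts over all libraries, and the rows of Pcsk2os1 and Pcsk2os2 on its opposite strand held 141543 and 141784. Rows are therefore given below, where first named, with the gene whose exons they overlap on the opposite strand. A row first named without such a gene overlaps no exon there.

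**Figure D1:**
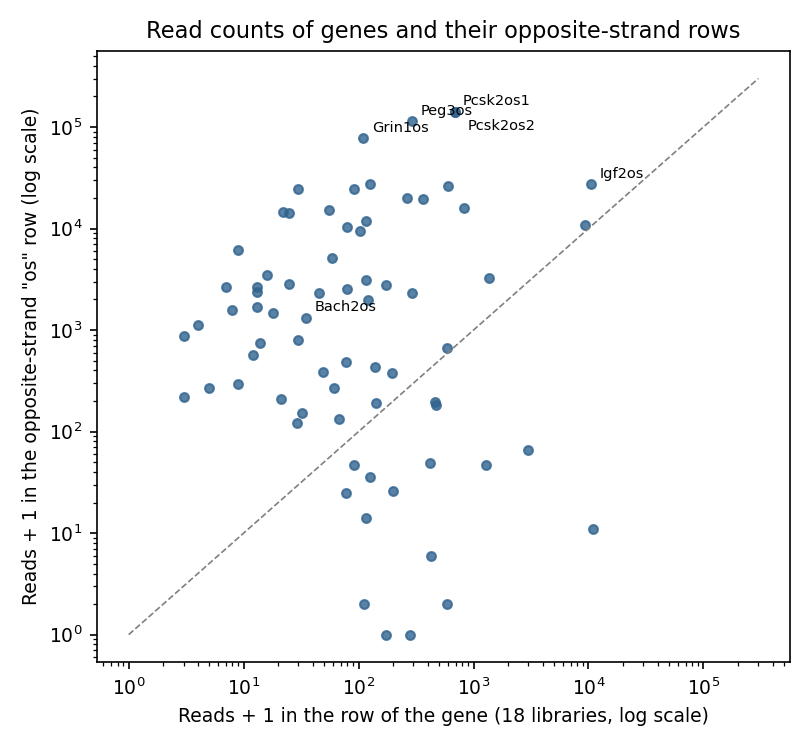
Counts over all 18 libraries of each opposite-strand row (vertical axis) against the gene it faces (horizontal axis), both on log scales and plotted as counts plus 1; each point is 1 of 72 pairs with at least 100 counts, and the dashed line marks equal counts. In 56 pairs the opposite-strand row lies above the line.

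The cytokine mix alone was compared with vehicle. The row of Mir6381, opposite the interferon-induced GTPase gene Gbp2, rose most of all rows tested. Other rows nearly absent in vehicle rose with it. The row of Mir6381 (gene ID 102465200, chromosome 3, 142623860 to 142623946), which overlaps 24 bp of an exon of Gbp2, went from 1.51 ± 2.62 to 41739 ± 1963 CPM, a ratio of 23570 (interval 8066 to 114300) on 3 counts in vehicle. The row of Gbp2 itself, an exon of which overlaps Mir6381 on the opposite strand, rose at least 108-fold from 0 counts. That of Cxcl9, a T cell chemokine gene with no gene opposite, rose at least 124-fold, also from 0 counts. The row of Gdnf, a neurotrophic factor gene with no gene opposite, rose at least 63.2-fold. Ratios on 1 count in vehicle were 445 (interval 79.3 to 17610) for Tmem200a, opposite Gm9767, and 436 (interval 77.7 to 17260) for Mb, opposite Apol6. The rows of 3110062M04Rik, opposite Tmem140 (8.68 ± 0.18, adjusted p = 1.9e-37 by edgeR), Numa1, opposite the interleukin-18 binding protein gene Il18bp (5.08 ± 0.14, adjusted p = 2.6e-33), and Parp9, opposite the ubiquitin ligase gene Dtx3l (3.86 ± 0.13, adjusted p = 1.7e-28), rose as well.

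In all, cytokines changed 327 of 3302 rows tested, 212 higher and 115 lower, and 175 of the changes were at least 2-fold. The lower rows numbered 75 without vehicle 1. Of the interferon response list of 44 genes, 15 of 16 measured rows rose, and 16 when adjusted over the list alone. Its median log2 fold change was 5.22, or 4.42 with the 8 members at 0 counts in vehicle set to their lower bound (adjusted p = 3.3e-23 by camera and 0.00889 with an estimated correlation, fry adjusted p = 2.7e-06). These 8 members passed the count filter only through other groups, which favours a high share of rising rows. The share in the DFMO and DENSpm backgrounds below has the same limit. Gbp7, with no gene opposite, rose by 4.27 ± 0.42, adjusted p = 2.7e-11. Of the antigen presentation list, 9 of 11 rows rose and 11 when adjusted over the list alone, with a median of 3.58 (adjusted p = 4.0e-15 by camera and 6.0e-04 with an estimated correlation). The row of H2-Q4, opposite Gm11131, rose by 3.64 and that of H2-T22, opposite A930015D03Rik, by 3.58. The row of Tap1, opposite the immunoproteasome gene Psmb9, rose by 4.93. It held 0, 7 and 0 counts in the vehicle libraries, and its change ran from 4.27 to 9.05 over the fits without 1 library. Taken by the gene opposite, 6 of 7 antigen presentation rows rose (adjusted p = 1.2e-10 by camera and 0.00122 with an estimated correlation), among them A930015D03Rik opposite H2-T22 (5.52) and Emc9 opposite the proteasome activator gene Psme1 (3.80). Both rows opposite NF-kB list genes rose, Psd opposite Nfkb2 by 1.92 ± 0.12, adjusted p = 1.8e-17 and Zmynd15 opposite Cxcl16 by 3.75 (adjusted p = 4.5e-04 by camera and 0.0238 with an estimated correlation).

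The rows of Ins2 and Chga fell. Ins2, an insulin gene with no gene opposite, stood at 100.2 ± 53.4 CPM with cytokines and 337 ± 72.8 without (-1.75 ± 0.27, adjusted p = 2.8e-06 by edgeR). Chga, which encodes a granule protein and has no gene opposite, changed by -0.62 ± 0.13, adjusted p = 3.7e-04. The share of counts in ribosomal protein rows was lower too: 0.0879%, 0.105% and 0.0969% with cytokines against 0.134%, 0.127% and 0.163% in vehicle. Whether a smaller share of reads counted on the own strand accounts for part of these falls was not tested. This limit also holds for Ins2 and other rows with no gene opposite in the comparisons below. Of the beta cell list 3 of 20 rows fell, 3 when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.0807 by camera and 0.437 with an estimated correlation). The rows of Pcsk2os1 and Pcsk2os2, opposite Pcsk2, fell by 0.50 and 0.54 on the log2 scale. They lie opposite the same gene and were the 2 calls among 5 rows opposite beta cell genes, so the list test counts Pcsk2 2 times (2 adjusted over the list alone, adjusted p = 0.00672 by camera, a call lost at 0.107 with an estimated correlation). Rows opposite the transcription factor gene Bach2 (Bach2os, -1.52), the cytochrome oxidase gene Cox6a2 (Itgad, -1.45), the angiotensin-converting enzyme gene Ace (Gm11651, -1.36) and the potassium channel subunit gene Kcnmb4 (Kcnmb4os2, -1.24) fell too. Of genes with larger changes on few counts, Ece1 stood at 3 counts against 67 (ratio 17.8 (interval 5.83 to 88.4)), and Gng12, opposite 4930597O21Rik, changed by -2.90.

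Single rows of stress and cell cycle genes changed, while these lists, taken by row symbol, did not pass camera. The row of Ddit3, which lies opposite Mars, the methionyl-tRNA synthetase gene, rose by 0.53, and the row of Mars, opposite Ddit3, which encodes the stress factor CHOP, rose by 0.73. Of the integrated stress response list 1 row rose and 1 fell of 24 (1 and 1 adjusted over the list alone; adjusted p = 0.361 by camera and 0.437 with an estimated correlation). Of 11 ER chaperone rows 1 rose and 2 fell (1 and 3 adjusted over the list alone; adjusted p = 0.0807 by camera and 0.211 with an estimated correlation), and the list fell by fry (adjusted p = 5.2e-04), which does not set a list against the other rows. The row of Pdia6, opposite Atp6v1c2, changed by -2.73. Taken by the gene opposite, 0 of 4 ER chaperone rows were called (adjusted p = 0.856 by camera and 0.514 by fry). Of 10 cell cycle rows 1 fell, the mitotic kinase gene Aurka (-1.68), and 1 rose and 2 fell when adjusted over the list alone (adjusted p = 0.361 by camera and 0.437 with an estimated correlation). Taken by the gene opposite, 2 of 4 cell cycle rows fell (2 adjusted over the list alone; adjusted p = 0.0304 by camera, a call lost at 0.102 with an estimated correlation). By edgeR, 0 rows changed in the lists for polyamine metabolism (9 measured, 1 at unadjusted p under 0.05), NF-kB targets (3, 0), cholesterol synthesis (3, 0), NRF2 (4, 0), oxidative phosphorylation (3, 1), ribosome biogenesis (10, 0), glycolysis (10, 1), other islet cells (2, 0), non-endocrine cells (1, 0) and disallowed genes (2, 0). The lowest camera adjusted p of these lists was 0.531. These counts are by row symbol. Taken by the gene opposite, the 1 NRF2 row rose by 0.45, besides the NF-kB rows above. The 1 row opposite a disallowed gene changed by -1.86, a call only when adjusted over the list alone. In the polyamine, cholesterol, oxidative phosphorylation, ribosome biogenesis and glycolysis lists 0 rows were called that way. No row of the p53 and mitochondrially encoded lists passed the count filter.

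**Figure D2:**
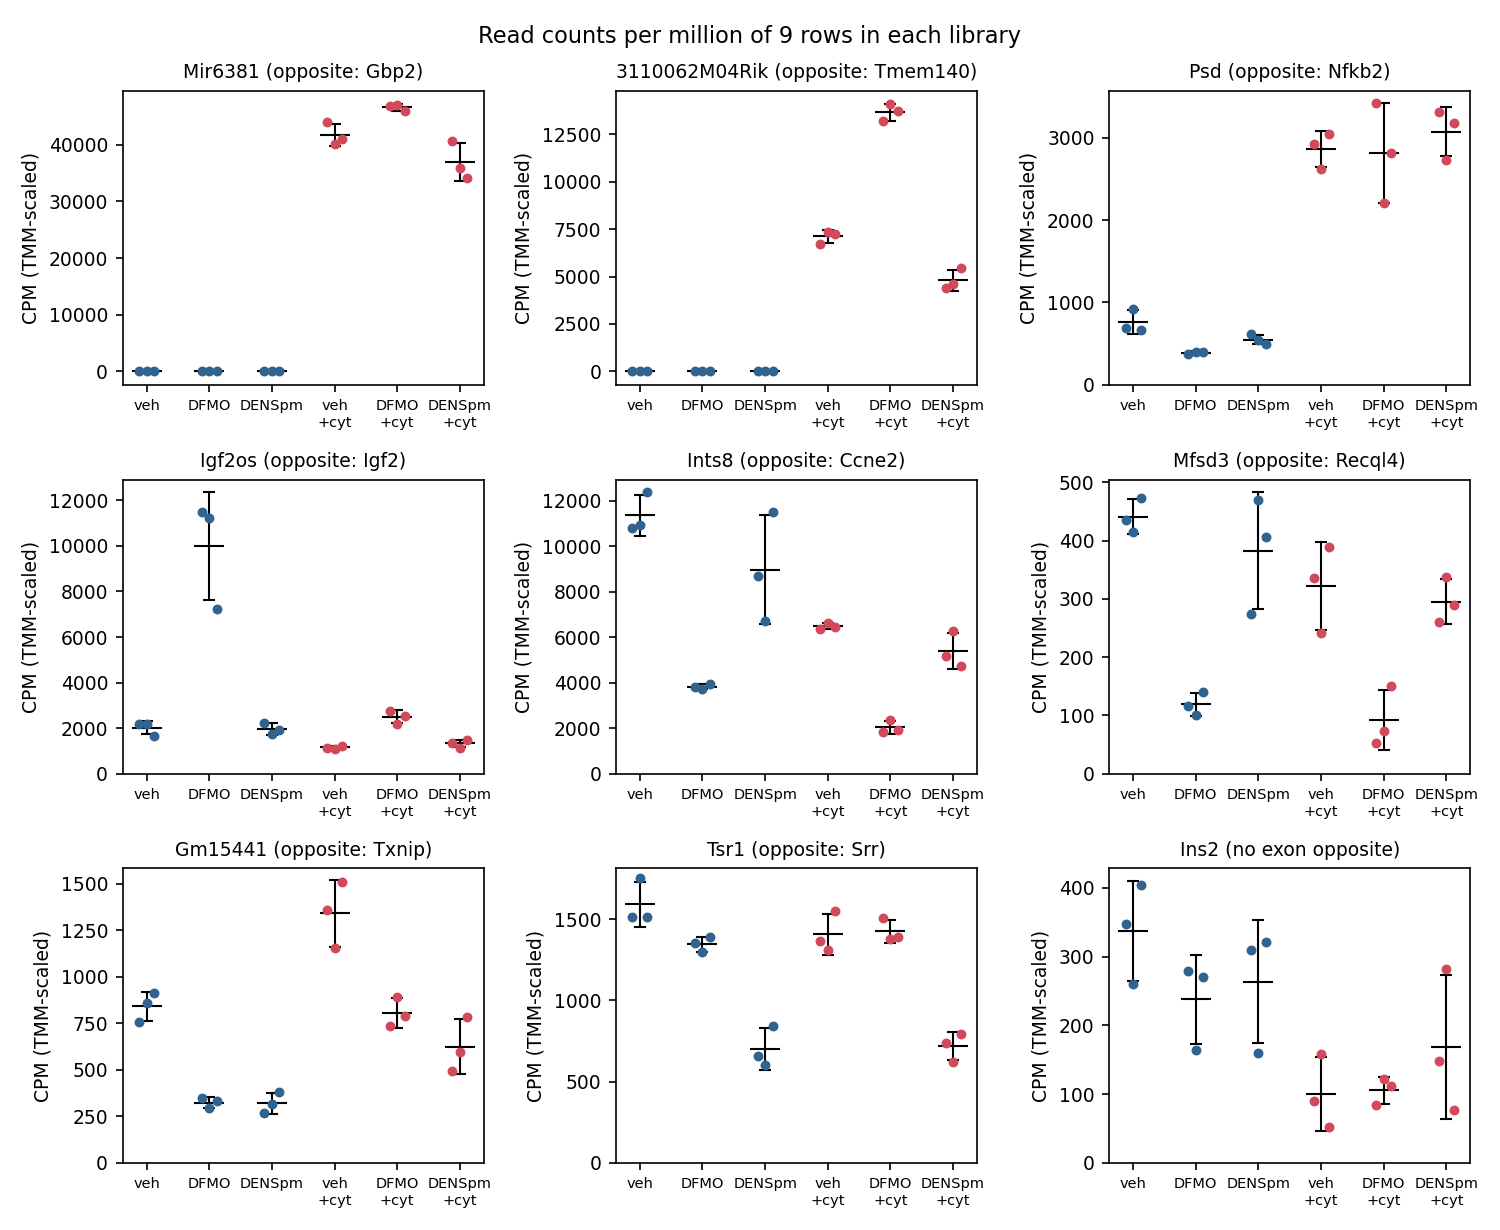
CPM of 9 rows in each library (points; horizontal axis, the 6 groups; vertical axis, CPM from 0), with the mean and SD of 3 libraries per group, blue without and red with cytokines; the gene on the opposite strand stands in each title. The Mir6381 row averages 41739 ± 1963 CPM in vehicle with cytokines against 1.51 ± 2.62 without, and the Ints8 row 3832 ± 101 in DFMO against 11370 ± 897 in vehicle.

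DFMO was compared with vehicle without cytokines. A row opposite a growth factor gene rose, and the rows opposite Ccne2 and Recql4 fell. The row of Igf2os (gene ID 111975, chromosome 7, 142659693 to 142670356), which overlaps 98 bp of exons of Igf2, the insulin-like growth factor 2 gene, stood at 9981 ± 2369.5 CPM with DFMO and 2026 ± 302 in vehicle (2.32 ± 0.12, adjusted p = 2.3e-20 by edgeR). Over all libraries the Igf2os row held 27321 counts and the Igf2 row itself 10479, and in vehicle 1 they held 1228 and 1214. The Igf2os row is therefore a less clear reading of the gene it faces than most pairs above. The change of the Igf2 row is not given here. The row of Ints8 (gene ID 72656, chromosome 4, 11199158 to 11254258), which overlaps 609 bp of exons of the cyclin E2 gene Ccne2, stood at 3832 ± 101 against 11370 ± 897 CPM (-1.55 ± 0.09, adjusted p = 3.2e-18). The row opposite the DNA helicase gene Recql4 (Mfsd3, -1.87 ± 0.24, adjusted p = 4.9e-08) fell, as did the row of Gm15441, opposite the thioredoxin-interacting protein gene Txnip (-1.36 ± 0.14, adjusted p = 6.8e-11).

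DFMO changed 482 of 3302 rows tested, 266 higher and 216 lower, 231 of them at least 2-fold. The higher rows numbered 172 without DFMO 2. Other rows that rose lay opposite Plekha6 (Gm19461, 2.71), C1qtnf1 (Gm11747, 1.51), the proton channel gene Hvcn1 (Tctn1, 1.28), Yif1a (Cnih2, 1.26) and the lysosomal protease gene Ctsz (Nelfcd, 1.23). Rows opposite Lypd1 (Gpr39, -2.20) and Iah1 (Adam17, -1.57) fell. Among rows with few counts, that of the purinergic receptor gene P2ry1, opposite Gm37035, rose at least 24.6-fold from 0 counts, Rpl7l1 rose by 3.25, Ifnlr1 stood at 27 counts against 1 (ratio 32.1 (interval 5.29 to 1314)), and Atad2 was at least 16.3-fold lower, at 0 counts with DFMO. By the gene opposite, 2 of 4 cell cycle rows fell, Ints8 and Exosc9, which lies opposite the cyclin A2 gene Ccna2 (-0.64), with a median of -0.60 for the list (2 adjusted over the list alone; adjusted p = 0.0184 by camera, a call lost at 0.140 with an estimated correlation). The row of Ccna2 itself, opposite Exosc9, changed by -0.44, the 1 call among 10 rows of the list taken by symbol (1 adjusted over the list alone; adjusted p = 0.780 by camera and 0.891 with an estimated correlation), and that call was lost without vehicle 3.

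Of the polyamine list 9 rows were measured, of which 2 rose and 1 fell, the same numbers as when adjusted over the list alone (adjusted p = 0.780 by camera and 0.899 with an estimated correlation). These were Arg2 (0.87), Dhps (0.91) and Oaz3 (-0.53), which lie opposite Vti1b, Wdr83 and Tdrkh, genes outside the polyamine pathway. The Arg2 call was lost without vehicle 1 or 2 or DFMO 1 or 3, the Dhps call without vehicle 1 or 3 or DFMO 2 or 3, and the Oaz3 call without any 1 library except DFMO 1. Taken by the gene opposite, 1 of 2 polyamine rows fell (1 adjusted over the list alone), with a median of -0.761. That list fell by fry (adjusted p = 0.0475) and not by camera (adjusted p = 0.329 and 0.412 with an estimated correlation). Odc1, the gene of the enzyme that DFMO inhibits, has no gene opposite and held 16 counts with DFMO and 14 in vehicle (0.46 ± 1.14, adjusted p = 0.878), a standard error that leaves all but large changes undetected. The rows of Pcsk2os1 and Pcsk2os2, both opposite Pcsk2, rose by 0.57 and 0.58. They were the 2 calls among 5 rows opposite beta cell genes (3 adjusted over the list alone, adjusted p = 0.0790 by camera and 0.317 with an estimated correlation, fry adjusted p = 0.0142). Ins2 stood at 238 ± 64.4 CPM against 337 ± 72.8 (-0.49 ± 0.25, adjusted p = 0.213), which did not pass. Of the antigen presentation list 2 rows rose and 1 fell of 11 (2 and 1 adjusted over the list alone; adjusted p = 0.780 by camera and 0.891 with an estimated correlation), with Tapbp, opposite Gm19412, at 1.29. In the interferon list edgeR called 0 of 16 rows, with 2 at unadjusted p under 0.05 and a camera adjusted p of 0.862. The row of Psd, opposite Nfkb2, fell by 0.94 and that of Mars, opposite Ddit3, by 0.67 on the log2 scale.

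With cytokines present, the rows opposite Ccne2 and Recql4 again fell with DFMO. The Ints8 row, opposite Ccne2, stood at 2038 ± 283 CPM in DFMO with cytokines against 6483 ± 131 in vehicle with cytokines (-1.68 ± 0.09, adjusted p = 6.4e-19 by edgeR). Rows opposite Recql4 (Mfsd3, -1.79), the recombination gene Rad54l (Lrrc41, -1.74 ± 0.20, adjusted p = 2.6e-09), and the kinetochore genes Oip5 (Nusap1, -1.56) and Zwilch (Lctl, -1.42) fell. Rows opposite the intermediate filament gene Sync (Rbbp4, 1.36 ± 0.15, adjusted p = 1.7e-09), Fbxl2 (Ubp1, 1.30), Mast4 (1700099I09Rik, 1.14) and Tmem140 (3110062M04Rik, 0.93) rose. The row of Il21, opposite Gm12534, rose at least 32.0-fold from 0 counts, and Acyp2 stood at 62 counts against 2 (ratio 32.0 (interval 8.49 to 270)).

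DFMO changed 365 of 3302 rows tested, 174 higher and 191 lower in the presence of cytokines. By the gene opposite, 2 of 4 cell cycle rows fell (2 adjusted over the list alone; adjusted p = 0.00560 by camera, a call lost at 0.0849 with an estimated correlation). The row of H2-T22, opposite A930015D03Rik, fell by 0.85, the 1 call among 11 antigen presentation rows (1 adjusted over the list alone; adjusted p = 0.699 by camera and 0.741 with an estimated correlation), and the row of Oaz3, opposite Tdrkh, by 0.78. Across 3302 rows the DFMO effects without and with cytokines correlated at r = 0.435, with 110 rows raised and 107 lowered in both, where independent lists of the same lengths would share 14.02 and 12.5, and 2 rows changed in opposite directions. These comparisons share no library, and the correlation is across genes, which are not independent replicates.

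**Figure D3:**
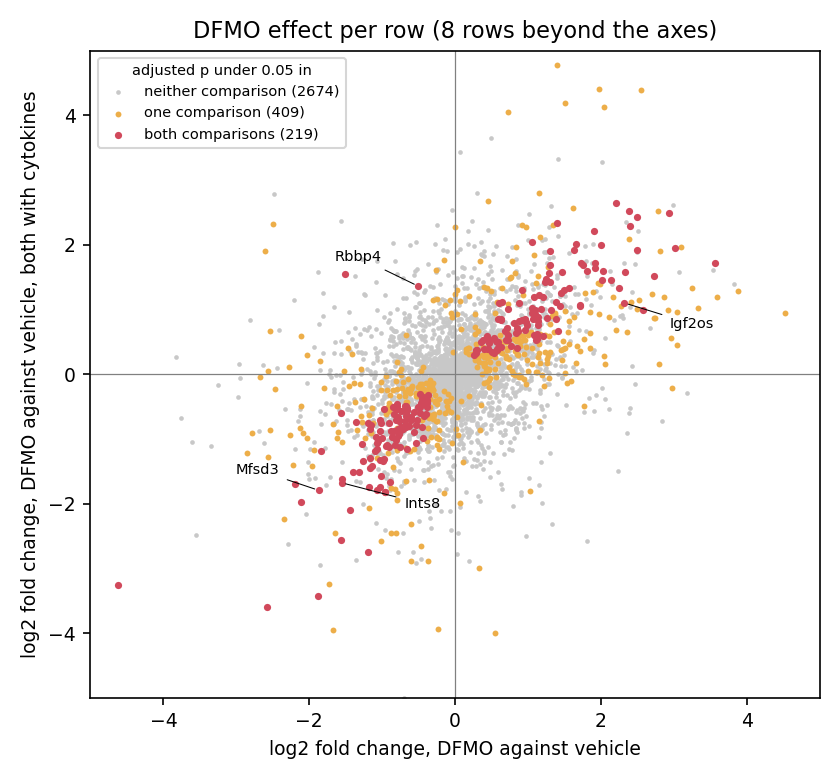
Log2 fold change of each tested row with DFMO without cytokines (horizontal axis) and with cytokines (vertical axis); colours mark rows changed in neither (2674), in 1 (409) or in both comparisons (219), and 8 rows lie beyond the axes. Ints8 and Mfsd3 lie low on both axes, and Igf2os lies high on both.

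DENSpm was compared with vehicle without cytokines. The rows that fell most firmly lay opposite Txnip and Srr. The row of Gm15441 (gene ID 100038464, chromosome 3, 96555765 to 96566801), overlapping 606 bp of exons of Txnip, stood at 320.2 ± 56.9 CPM with DENSpm and 841 ± 79.3 in vehicle (-1.38 ± 0.17, adjusted p = 1.2e-05 by edgeR). The row of Tsr1 (gene ID 104662, chromosome 11, 74898071 to 74909342), overlapping 1240 bp of exons of the serine racemase gene Srr, stood at 701 ± 127 against 1593 ± 139 CPM (-1.18 ± 0.15, adjusted p = 1.2e-05). Other rows that fell lay opposite the mitochondrial ribosomal protein gene Mrpl24 (Rrnad1, -0.67), the splicing protein gene Snrpf (4933408J17Rik, -0.61) and Fam216a (Vps29, -0.59). Rows opposite the nucleotidase gene Nt5m (Cops3, 0.85), Cdca7l (Dnah11, 0.64), Mars (Ddit3, 0.63) and the RNA helicase gene Ddx49 (Homer3, 0.62) rose.

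DENSpm changed 18 of 3315 rows tested, 11 higher and 7 lower, and 371 rows had an unadjusted p under 0.05. The count moved with single libraries: it was 2, 3 and 4 without vehicle 1, 2 and 3, and 3, 32 and 28 without DENSpm 1, 2 and 3, and DESeq2 called 43 rows. Of the 16 named rows, Gm15441 and Tsr1 held in each of these 6 fits, and each of the other 14 was lost without vehicle 1. Of the integrated stress response list, taken by row symbol, 1 of 24 rows rose, Ddit3, which lies opposite Mars (1 adjusted over the list alone, adjusted p = 0.834 by camera and 0.967 with an estimated correlation). Taken by the gene opposite, the 1 row measured, Mars opposite Ddit3, changed by -0.21 and was not called. EdgeR called 0 of 16 interferon rows (4 at unadjusted p under 0.05; camera adjusted p = 0.960) and 0 of 3 rows of other islet cells (1 at unadjusted p under 0.05, 1 when adjusted over the list alone; adjusted p = 0.0467 by camera, a call lost at 0.261 with an estimated correlation). Odc1 held 14 counts in each group, Sat1, the catabolic acetyltransferase gene, held 8 with DENSpm and 4 in vehicle, and neither passed the filter. Among 2 rows opposite polyamine genes 0 were called, and 1 fell when adjusted over the list alone (adjusted p = 0.684 by camera and 0.883 with an estimated correlation). Ins2 stood at 264 ± 89.8 CPM against 337 ± 72.8 (-0.36 ± 0.38, adjusted p = 0.785), which did not pass.

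With cytokines, DENSpm lowered the rows of Gm15441, opposite Txnip (-1.10 ± 0.17, adjusted p = 2.9e-04 by edgeR), and Tsr1, opposite Srr (-0.97 ± 0.15, adjusted p = 2.9e-04), again. Rows opposite Khnyn (Sdr39u1, -1.19 ± 0.18, adjusted p = 2.9e-04) and Paqr3 (Bmp2k, -1.17 ± 0.17, adjusted p = 2.9e-04) fell. The row opposite Ddx49 (Homer3, 0.81 ± 0.14, adjusted p = 0.00174) rose. The row of Mars, opposite Ddit3, stood at 334 ± 20.9 CPM against 633 ± 144 (-0.91 ± 0.18, adjusted p = 0.00748), and the row of Particl, opposite the methionine adenosyltransferase gene Mat2a, changed by -0.68 ± 0.16, adjusted p = 0.0289. The Mars call was lost without vehicle with cytokines 3, and the Particl call without any 1 library except vehicle with cytokines 1. DENSpm changed 44 of 3315 rows tested, 19 higher and 25 lower with cytokines. The count was 12, 19 and 7 without vehicle with cytokines 1, 2 and 3 and 21 without each of the DENSpm with cytokines libraries, and DESeq2 called 82; of 20 named rows Gm15441, Tsr1, Sdr39u1, Bmp2k and Homer3 held in each of the 6 fits. Of the polyamine list, taken by row symbol, edgeR called 0 of 8 rows (1 adjusted over the list alone and 2 at unadjusted p under 0.05). That list fell by fry (adjusted p = 0.0418) and not by camera (adjusted p = 0.239). Taken by the gene opposite, 1 of 2 polyamine rows fell, Particl opposite Mat2a (1 adjusted over the list alone). As a set these 2 rows did not pass (adjusted p = 0.493 by camera, 0.970 with an estimated correlation and 0.223 by fry).

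The DENSpm effects without and with cytokines correlated at r = 0.181 across 3315 rows, with 2 rows raised and 4 lowered in both against 0.0631 and 0.0528 for independent lists. In the fit of all 18 libraries, DFMO and DENSpm effects, both against the same vehicle libraries, correlated at r = 0.387 without cytokines (covariance 0.284), where 20 simulations of unchanged groups gave a mean r of 0.486 and a covariance of 0.179. They shared 4 raised and 2 lowered rows, against 0.724 and 0.644 for independent lists, and 2 rows changed in opposite directions. With cytokines r was 0.378 and the covariance 0.275, against simulated means of 0.505 and 0.201, with 4 raised and 8 lowered rows shared against 0.847 and 1.24. There 0 rows changed in opposite directions. The highest simulated covariances were 0.191 and 0.228, below both observed values, and simulated groups shared 0 called rows. The observed covariances exceeded the simulated means by 0.105 and 0.0746. With 3 control libraries the controls could not be split, and part of the excess of shared rows may come from the shared controls.

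The 2 compounds were compared directly within each cytokine condition; they were given at different concentrations, 10 µM and 5 mM. The rows opposite Ccne2 and Recql4 were higher with DENSpm than with DFMO. Without cytokines the differences, DENSpm minus DFMO, were 1.23 ± 0.14, adjusted p = 9.3e-09 for Ints8 (opposite Ccne2) by edgeR and 1.68 ± 0.25, adjusted p = 4.1e-06 for Mfsd3 (opposite Recql4). The row of Rufy2, opposite the RNA-binding protein gene Hnrnph3, was higher with DENSpm (1.62 ± 0.11, adjusted p = 1.1e-14), and those of Igf2os, opposite Igf2 (-2.35 ± 0.15, adjusted p = 8.6e-16), and Neurl2, opposite the lysosomal gene Ctsa (-1.58 ± 0.18, adjusted p = 1.4e-08), were lower. For Gm15441, opposite Txnip, the difference was -0.01 ± 0.17 (adjusted p = 0.974); a threshold that is missed does not show that the compounds act alike on this row. Tsr1, opposite Srr, was lower with DENSpm (-0.94 ± 0.14, adjusted p = 2.4e-06).

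In all 414 of 3713 rows tested, 217 higher and 197 lower with DENSpm, were called. The count was 269 without DFMO 2, of which 134 were higher. Of the polyamine list 2 of 10 rows were lower, Dhps (-1.15) and Arg2 (-0.87), which lie opposite Wdr83 and Vti1b (2 adjusted over the list alone; adjusted p = 0.854 by camera and 0.993 with an estimated correlation). The Dhps call was lost without DFMO 2 or DENSpm 3 and the Arg2 call without any 1 library except DFMO 2. Of 4 rows opposite cell cycle list genes 2 were higher (2 adjusted over the list alone; adjusted p = 0.270 by camera and 0.456 with an estimated correlation; fry adjusted p = 0.0170). With cytokines these were 377 of 3713 rows tested, 199 higher and 178 lower with DENSpm. Rows opposite Oip5 (Nusap1, 1.98 ± 0.22, adjusted p = 1.1e-08), Rad54l (Lrrc41, 1.84), the Fanconi anaemia gene Fanci (Polg, 1.73) and Ccne2 (Ints8, 1.41) were higher with DENSpm, and rows opposite Sync (Rbbp4, -1.80) and Tmem140 (3110062M04Rik, -1.51 ± 0.17, adjusted p = 2.8e-08) were lower. The row of Mki67, a proliferation marker gene that faces only the body of another gene, held 39 counts with DENSpm and 0 with DFMO, at least 10.8-fold higher. The row of the mitotic kinase gene Aurka was lower (-1.56), a call lost without DFMO with cytokines 2 or DENSpm with cytokines 3. Of the cell cycle list by symbol 2 rows were higher and 1 lower of 15 (2 and 1 adjusted over the list alone; adjusted p = 0.952 by camera and 0.970 with an estimated correlation). Of the rows opposite cell cycle list genes 2 of 4 were higher (2 adjusted over the list alone; adjusted p = 0.0183 by camera, a call lost at 0.240 with an estimated correlation). Of the polyamine list 1 row was higher and 1 lower of 10 (1 and 1 adjusted over the list alone; adjusted p = 0.952 by camera and 0.970 with an estimated correlation).

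The cytokine response was measured again in cells that received DFMO. Rows of the interferon and antigen presentation lists rose here too. The row of Mir6381, opposite Gbp2, rose at least 22150-fold from 0 counts, Cxcl9 at least 115-fold, Gbp2 at least 94.5-fold, Gdnf at least 258-fold and the complement gene C2, opposite Zbtb12, at least 62.1-fold. Rows opposite Tmem140 (3110062M04Rik, 9.34 ± 0.18, adjusted p = 8.1e-39 by edgeR), Psme1 (Emc9, 4.18), Dtx3l (Parp9, 4.08) and Nfkb2 (Psd, 2.82 ± 0.13, adjusted p = 4.5e-23) rose. The rows of Igf2os, opposite Igf2 (-2.02 ± 0.12, adjusted p = 3.6e-19), Il12rb2, opposite Serbp1 (-2.33), Ins2 (-1.19 ± 0.28, adjusted p = 0.00133) and Pdx1, a beta cell transcription factor gene (19.8 ± 11.9 against 80.1 ± 3.63 CPM, adjusted p = 0.00105), fell.

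Cytokines changed 433 of 3302 rows tested, 232 higher and 201 lower in DFMO. The lower rows numbered 132 without DFMO 2. Taken by row symbol, the integrated stress response list fell by fry (adjusted p = 0.00758) and not by camera (adjusted p = 0.0961), with edgeR calling 0 of 24 rows and 6 at unadjusted p under 0.05. Taken by the gene opposite, the 1 row measured, Mars opposite Ddit3, was called and rose by 0.81. Of the interferon list 15 of 16 rows rose (16 adjusted over the list alone; median 6.14, or 4.03 with members at 0 counts at their bound; adjusted p = 1.1e-18 by camera and 0.0175 with an estimated correlation), and of the antigen presentation list 7 of 11 (8 adjusted over the list alone; adjusted p = 1.2e-08 by camera and 0.00473 with an estimated correlation). Of the beta cell list 5 of 20 rows fell (1 rose and 5 fell when adjusted over the list alone; adjusted p = 0.0868 by camera and 0.539 with an estimated correlation). Taken by the gene opposite, 4 of 5 rows fell, 2 of them opposite Pcsk2 (4 adjusted over the list alone; adjusted p = 0.00272 by camera, a call lost at 0.0783 with an estimated correlation). Taken by row symbol, the ER chaperone list fell as a set (camera adjusted p = 0.0271, median -0.82, fry adjusted p = 3.3e-05). That camera call was lost with an estimated correlation (adjusted p = 0.0967). Of its 11 rows 1 was called, Pdia6, opposite Atp6v1c2. Taken by the gene opposite, 0 of 4 ER chaperone rows were called (median -0.318, adjusted p = 0.424 by camera and 0.104 by fry). The Pdia6 call was lost without DFMO 2 or 3 or DFMO with cytokines 2, without a filter and in the fit of all 18 libraries.

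In cells that received DENSpm, cytokines raised the row of Mir6381 at least 19040-fold, Gbp2 at least 80.3-fold, Cxcl9 at least 73.1-fold, Gdnf at least 71.5-fold and Gbp3 at least 58.0-fold, each from 0 counts. Rows opposite Tmem140 (3110062M04Rik, 9.35 ± 0.30, adjusted p = 1.6e-20 by edgeR), Dtx3l (Parp9, 3.89), Psme1 (Emc9, 3.76) and Nfkb2 (Psd, 2.48 ± 0.15, adjusted p = 9.6e-14) rose, and rows opposite Bach2 (Bach2os, -2.35 ± 0.33, adjusted p = 6.2e-06), Serbp1 (Il12rb2, -1.80) and Fam120c (A230072E10Rik, -1.12) fell. Cytokines changed 246 of 3315 rows tested, 158 higher and 88 lower. Of the NF-kB list 1 of 5 rows rose (2 adjusted over the list alone; adjusted p = 0.589 by camera and 0.701 with an estimated correlation; fry adjusted p = 0.0312). Of the interferon list 14 of 16 rows rose (15 adjusted over the list alone; adjusted p = 3.6e-22 by camera and 0.00902 with an estimated correlation), and of the antigen presentation list 9 of 12 (10 adjusted over the list alone; adjusted p = 3.5e-12 by camera and 0.00294 with an estimated correlation). In the beta cell list 1 of 19 rows fell (1 adjusted over the list alone; adjusted p = 0.899 by camera and 0.944 with an estimated correlation), and Ins2 changed by -0.60 ± 0.39, adjusted p = 0.474, which did not pass. Nos2, the inducible nitric oxide synthase gene, held 0 counts without cytokines in each of the 3 backgrounds and 16, 18 and 8 counts with cytokines in vehicle, DFMO and DENSpm, at least 6.70-fold, at least 6.54-fold and at least 2.62-fold higher, but did not pass the filter. Ins1 went from 35 to 14 counts in vehicle and was not tested, and Amd1 held 0 counts and Smox 0 or 1 in every group.

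Whether DFMO altered the cytokine response was tested as an interaction. The rise of the Psd row, opposite Nfkb2, was larger in DFMO (2.82 against 1.92 in vehicle; interaction 0.91 ± 0.18, adjusted p = 0.00549 by edgeR). It began from a lower level without cytokines (-0.94 with DFMO) and ended at a similar one with cytokines (-0.03 ± 0.12, adjusted p = 0.911, not passed). The row of Rbbp4, opposite Sync, rose by 2.40 in DFMO and 0.53 in vehicle, the latter a call lost without vehicle 1 or vehicle with cytokines 3 (interaction 1.87 ± 0.22, adjusted p = 1.7e-07). The row of Igf2os, opposite Igf2, fell by 2.02 in DFMO and 0.81 in vehicle (interaction -1.22 ± 0.16, adjusted p = 4.1e-06), and that of Numa1, opposite Il18bp, rose less in DFMO (interaction -0.82 ± 0.19, adjusted p = 0.0322), a call lost in 7 of the 12 fits without 1 library, those without vehicle 1, vehicle with cytokines 1 or 3, DFMO 2 or 3, or DFMO with cytokines 2 or 3.

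DFMO altered the response in 14 of 3302 rows tested, 6 higher and 8 lower; Psd, Rbbp4 and Igf2os held in each of the fits without 1 library, whose counts ran from 5 to 19. DESeq2 called 25 rows and the fit of all 18 libraries 4. A row at 0 counts in both groups without cytokines gives no fold changes to compare, so neither interaction test could call it. Among such rows Gdnf held 49, 67 and 35 counts in vehicle with cytokines and 232, 236 and 243 in DFMO with cytokines. Il21 held 0 in each of the former and 25, 27 and 41 in the latter. For Cxcl9 the counts were 99, 113 and 84 against 62, 107 and 148. For DENSpm edgeR called 0 of 3315 rows, with 169 at unadjusted p under 0.05, and DESeq2 called 0. Of the antigen presentation list 1 of 11 rows had a smaller response in DFMO, Tapbp, opposite Gm19412 (-1.35; 1 larger and 2 smaller adjusted over the list alone; adjusted p = 0.333 by camera and 0.787 with an estimated correlation). The cytokine responses in vehicle and in DFMO which share no library, correlated at r = 0.708 across rows, with 150 raised and 79 lowered in both, against 14.9 and 7 for independent lists.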

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

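The test of the difference between cytokine responses was fixed before the data were examined; the weighing of strand in the last paragraph used tests chosen after the result was seen.

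The cytokine response differed between DFMO and vehicle in 14 rows, by the interaction term of edgeR (DFMO minus vehicle, log2 ± standard error). This term could not call rows at 0 counts in both groups without cytokines. Rows with a larger response in DFMO were Rbbp4 (opposite Sync) 1.87 ± 0.22, Psd (opposite Nfkb2) 0.91 ± 0.18, 1700020L24Rik (opposite Mmp28) 3.06 ± 0.61, 1700099I09Rik (opposite Mast4) 1.21 ± 0.29, Adam17 (opposite Iah1) 0.97 ± 0.23 and Abhd16b 4.51 ± 1.02, the last with no gene opposite. Rows with a smaller or more negative response were Igf2os (opposite Igf2) -1.22 ± 0.16, Myh7b (opposite Trpc4ap) -2.83 ± 0.60, Gm11747 (opposite C1qtnf1) -1.09 ± 0.24, Numa1 (opposite Il18bp) -0.82 ± 0.19, Tapbp (opposite Gm19412) -1.35 ± 0.32, Stab1 (opposite Nt5dc2) -0.99 ± 0.24, Krt10 (opposite Gm11940) -1.59 ± 0.40 and Ifi27l2a -0.64 ± 0.14, the last with no gene opposite and itself an interferon-induced gene. The cytokine changes behind the Myh7b value were 1.45 in vehicle and -1.39 in DFMO. Of the 12 named among these 14, only Rbbp4, Psd and Igf2os held in every fit without 1 library.

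Of 100 splits of the 12 libraries that kept group sizes, 10 gave at least 14 rows, the real split included. The highest other split gave 738 rows; it swaps the drug labels within the cytokine arm, so that the DFMO effect itself becomes the interaction, a structure of the samples. Since splits can carry the drug effect in this way, they do not decide whether chance gives 14 rows. For DENSpm the real count was 0, which each of the 100 splits reaches by construction (highest other 158, of the same kind), so nothing follows from it.

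The concentration of counts in rows opposite other genes was weighed. If reads of a strand-specific kit had been counted on the opposite strand, rows named for opposite-strand transcripts would exceed the genes they face, and 56 of 72 such pairs did, which is consistent with that explanation. Counting without regard to strand would leave ribosomal protein rows several percent of the counts, and their highest share over the 18 libraries was 0.163%. Abundant antisense transcription would add to the sense counts without removing them, and the lowest share of ribosomal protein rows was 0.0826%; both values argue against these explanations. Apart from antisense transcription no biological explanation was tested, since the pattern was present in all 6 groups.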

How the results depend on the processing

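The alternatives were chosen before the data were examined, except halved counts and the restriction to rows with an opposite exon. No named row reversed its direction under any alternative run. With a minimum absolute log2 fold change of 1, which removes smaller changes by construction, the counts were 175 for cytokines in vehicle, 231 for DFMO, 7 for DENSpm, 175 and 16 for DFMO and DENSpm with cytokines, 237 and 153 for cytokines in DFMO and DENSpm, 9 for the DFMO interaction, and 202 and 198 for DENSpm against DFMO without and with cytokines. The DENSpm count was least settled: against 18, it was 43 by DESeq2, 30 without a filter, 33 with a filter of 1 CPM in 3 libraries, 4 with only the groups compared and 31 with halved counts. With cytokines, against 44, it was 82 by DESeq2, 74 with only the groups compared and 67 with halved counts. The DFMO interaction count, against 14, was 25 by DESeq2 and 4 with all 18 libraries. The cause was not tested in these cases. All other totals of changed rows under the alternatives run lay within 1.5 times the count given above for the comparison. Other scalings moved the median log2 fold change of all rows by less than 0.02.

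Leaving out 1 library gave 228 to 291 rows for cytokines in vehicle, 332 to 389 for DFMO, 2 to 32 for DENSpm, 256 to 305 for DFMO with cytokines, 7 to 21 for DENSpm with cytokines, 323 to 386 and 186 to 253 for cytokines in DFMO and in DENSpm, 5 to 19 for the DFMO interaction, 0 to 0 for the DENSpm interaction, and 269 to 351 and 284 to 310 for DENSpm against DFMO without and with cytokines. Each of the 6 libraries moved the DENSpm counts by more than 1.5 times in both conditions, without DFMO 2 the difference between the compounds fell to 269, and the interaction count fell to 6 without vehicle 1, vehicle with cytokines 1 or DFMO with cytokines 3, 9 without vehicle with cytokines 3, 7 without DFMO 1, and 5 without DFMO 2 or DFMO with cytokines 2.

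The replicate numbers did not pair the libraries: over 642 rows and 15 pairs of groups, correlations of same-numbered libraries ran from -0.213 to 0.317, in 0 pairs of groups were all above 0.1, and 8 of 18 libraries correlated best with their own number. With the replicate number as a block the counts were 307 for cytokines in vehicle, 458 for DFMO, 23 for DENSpm, 357 and 40 for DFMO and DENSpm with cytokines, 417 and 249 for cytokines in DFMO and in DENSpm, 13 and 0 for the interactions, and 414 and 380 for DENSpm against DFMO without and with cytokines. The authors' library factors were not run for DENSpm against DFMO, since each table has its own; fits of only the groups compared are the same as the full fit for interactions; and controls were not split.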

Other observations

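The tests of cell cycle rows, of depth and of strand were chosen after the results were seen; the tests of spread and of the DENSpm libraries left out in turn, and the splits, were written before.

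Rows opposite cell cycle genes of a published list of 97 genes fell with DFMO. Of 8 such rows, 4 fell, among them Ints8 (opposite Ccne2), Gse1 (opposite the replication gene Gins2, -0.82) and Primpol (opposite the centromere gene Cenpu, -0.68). The median was -0.804 with DFMO and -0.78 with DFMO and cytokines, -0.594 with cytokines alone, and -0.0313 and -0.0881 with DENSpm without and with cytokines. DENSpm minus DFMO gave a median of 0.692 over 9 rows without cytokines and 0.849 with cytokines, and 4 rows were higher in each case. The Primpol call with DFMO was lost without vehicle 1 or DFMO 1. That row also fell with cytokines alone (-0.82).

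This pattern was weighed against technical explanations. Under 3 scalings the median of the set was at most -0.804, so library scaling does not account for it. In 10000 random sets of equal size and abundance, 5 had a median as low as with DFMO, though the list was picked after the fall of the Ints8 row had been seen. Leaving out any of the 6 libraries left a median of at most -0.749, so no single library carries it. The fall was not particular to DFMO: 1 random set was as low as the median with cytokines alone, and for cytokines in DFMO (median -0.446) and in DENSpm (-0.483) 130 and 37 were. No biological explanation was tested.

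DFMO changed more rows than DENSpm, 482 against 18 without cytokines. A larger spread between DENSpm libraries (coefficient of variation within the group 0.345 against 0.272) could lower their count. With the spread shared by all 18 libraries, the count for DFMO without cytokines was still 13.9 times that for DENSpm. In that fit 376 and 27 rows were called without cytokines, and 269 and 57 with cytokines, a smaller ratio. Without cytokines, DENSpm libraries held 1.04 times the mean total of DFMO libraries, so lower depth does not account for it. There the highest DENSpm count over the 6 fits without 1 library was 32. The concentrations, 5 mM and 10 µM, differ, and whether the DENSpm dose was too low was not tested.

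Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split alone gave as many rows in each comparison (1 of 10). Every other split mixes libraries of both groups, so a real difference widens the spread within its groups. Low counts in the other splits follow from this, and they do not decide whether chance gives the real count. The real and the highest other counts were 327 and 0 for cytokines in vehicle, 482 and 0 for DFMO, 18 and 1 for DENSpm, 365 and 0 for DFMO with cytokines, 44 and 0 for DENSpm with cytokines, 433 and 0 for cytokines in DFMO, 246 and 0 for cytokines in DENSpm, and 414 and 0 and 377 and 0 for DENSpm against DFMO without and with cytokines.

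Libraries of a group differed by more than counting error. The chi-square per degree of freedom ran from 3.43 to 10.7 over pairs of replicates, with the highest value for DENSpm 2 against DENSpm 3. If each read pair had added 2 counts, counting error alone would give a value of 2, so no pair was as close as copies of 1 library would be.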
